A study of Mus musculus with 2 samples.

How the data were processed

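CUT&RUN maps where a protein sits on chromatin: an antibody tethers a nuclease to the protein in permeabilised nuclei, and the DNA released by cutting is sequenced. Here it was applied to nuclei of the paraventricular nucleus of the hypothalamus (PVN) of wild-type mice, per the labels. The series has 2 samples, 1 with an antibody against Otp (Orthopedia, a homeodomain transcription factor) and 1 with IgG, the antibody control that has no target. The groups were taken from the antibody label. There is 1 library per group, so no difference between them has a replicate check and no test across samples was possible.

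Each sample has 1 peak list in the narrowPeak layout, made by the authors. Per the submitters' processing notes, Trimmomatic, Bowtie2, Picard, SAMtools and MACS2 were used with the mouse build mm10. Versions, settings, the handling of duplicate reads and the use of a control library in peak calling are not given in the sources used here. Regions of each file were called per sample. The deposited fold enrichment (a ratio, at the summit, over the peak caller's own background estimate) and the deposited −log10 p and −log10 q are the authors' values. They were used to rank regions within a list, are set side by side between the lists without a test, and gave the pileups below. The smallest deposited −log10 q was 2.01 in the Otp list and 2.03 in the IgG list, just above 2. The deposited display score, which repeats the −log10 q, was not used. Numbers of reads per library are not in the peak lists, so total depth is unknown.

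Pileups were worked out from the deposited values. MACS2 defines fold enrichment as pileup plus 1 divided by background plus 1, and p as the Poisson tail above the pileup, so each region's fold and p give both numbers if the pileup is whole. A pileup was accepted if a whole number matched the deposited −log10 p within 0.001 and the next whole number missed by over 0.005. This gave a pileup for 11182 Otp regions (98.3%) and 262 IgG regions (90.0%). Of 2000 Otp regions drawn at random, 98.9% had a solution, against 0.45% after their −log10 p was shifted at random. A tag is a read or a fragment, whichever the authors' caller counted. The lowest background value shared by at least 3 regions was taken as the genome background of a library. Intervals of pileups are 95% Poisson intervals and those of shares are 95% exact (Clopper-Pearson) binomial intervals. Both cover counting error only, since reads amplified by PCR are not independent molecules.

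Gene positions came from an NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes. Its 21887 protein-coding genes on nuclear chromosomes have a start and an end but no strand and no exons. A promoter therefore could not be separated from the far end of a gene, and regions were counted at a gene end when the summit lay within 1 kb of either end. The planned division into exons and introns, the search for the homeodomain motif at summits and the matching of genes on CpG density need a genome sequence or exon models and were not run here. Random positions, 10000 in number, were drawn on the chromosomes of the Otp regions between the outermost gene ends. Mitochondrial regions were left out of all counts at genes.

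The lists were compared by overlap of at least 1 bp (bedtools 2.31.1). No entries overlapped within a file. Gene lists, 14 in number with 180 genes that were all found in the table, were fixed before the data were examined. They hold neuropeptides and transcription factors of the PVN, energy balance genes, glutamatergic, pan-neuronal and GABAergic genes, markers of neighbouring hypothalamus, astrocytes, oligodendrocytes, microglia and vascular or ependymal cells, immediate early genes, housekeeping genes and genes of non-neural organs. For each list, the number of genes with a region at an end was placed among 10000 random lists matched on decile of gene length. Ties, random lists with the same number of such genes, were split evenly between below and above. A list with no such gene thus takes its percentile from ties alone. A list stood apart above the 97.5 or below the 2.5 percentile. This describes the peak list and is no p-value. The named genes were also fixed beforehand: Mc4r and Otp, up to 4 members per list in order of fold enrichment, the 15 Otp regions at gene ends and the 10 anywhere with the highest −log10 q and no IgG overlap, and the 5 highest IgG regions. Genes named as lacking a region, and neighbours of listed genes, were chosen after their values were seen. So were the pileup calculation, the scaling of pileups between the libraries and the stretch of chromosome 9, whose bound was widened to 4 Mb after a narrower one had been counted. The strand of Mc4r is general knowledge and not from the gene table. Alternatives were stricter thresholds, other overlap rules, windows of 500 bp and 5 kb, all annotated genes, and random lists without matching.

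The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. On simulated data, 99.1% of 970 pileups were recovered and 100% of these were right. These data were built with the formulas that the recovery inverts, so they do not check the formulas themselves. The simulated pileups were also lower than those of the strongest regions. Of 200 unchanged lists of 15 genes, 5.5% fell outside the percentile bounds, and 74% of 200 lists with 4-fold higher odds lay above the upper bound.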

Results

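CUT&RUN libraries from the adult PVN were compared between an Otp antibody and an IgG control, with 1 library each. The Otp list held 11379 regions with a median width of 131 bp, and the IgG list held 291 regions with a median width of 109 bp. The median fold enrichment was 6.97 (interquartile range 5.79 to 8.84) in the Otp list and 7.60 (5.68 to 10.8) in the IgG list. The genome background was 0.512 tags in the Otp library and 0.0873 tags in the IgG library, a ratio of 5.86. Neither list has a replicate. Among the regions with a pileup, 11182 of the Otp list and 262 of the IgG list, the median at a summit was 13 tags in both. The smallest was 6 tags in the Otp list and 4 tags in the IgG list. The 5 highest IgG regions and the Otp regions over them had no pileup, so these values leave them out.

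The series asks whether Otp, a homeodomain factor needed for the development of PVN neurons, binds at the promoter of Mc4r, the melanocortin receptor through which the PVN restrains food intake. The Otp list held a region at Mc4r and the IgG list held none. Mc4r (gene ID 17202) spans positions 66857705 to 66860487 of chromosome 18 in mm10 and is transcribed from the reverse strand, so that its upper end is its start. The region covered positions 66860511 to 66860593, just outside the gene, with its summit 62 bp from that end. Its fold enrichment was 7.51 and its −log10 q was 7.86, as the authors' caller gave them. It was the single Otp region within 100 kb of the gene. The pileup at its summit was 11 tags (95% Poisson interval 5.49 to 19.7) over a local background of 0.598 tags. By −log10 q it ranked 5572 of 11379, close to the middle of the list. Scaled by the ratio of the background values, 11 tags corresponded to 1.88 tags in the IgG library, below the 4 tags of its weakest region with a pileup. Scaled by the median ratio at regions of both lists (0.305), they corresponded to 3.36 tags. A difference from IgG at Mc4r was therefore not detectable at this depth. The same decile of length held 2189 protein-coding genes, Mc4r included. Of these, 430 (19.6%, 95% interval 18 to 21.4%) had an Otp region at either end.

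The Otp gene itself (gene ID 18420, chromosome 13, positions 94875636 to 94885125) had no Otp region within 1 kb of either end. The IgG control, in contrast, had 2 regions inside the gene. They covered positions 94877115 to 94877529, with 27 tags at the summit (17.8 to 39.3), and positions 94883106 to 94883575, with 31 tags (21.1 to 44.0). Their fold enrichments were 15.2 and 16.6. The Otp list held a region of 7 tags (2.81 to 14.4) at positions 94877158 to 94877284, within the first of these, and none at the second.

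**Figure D1:**
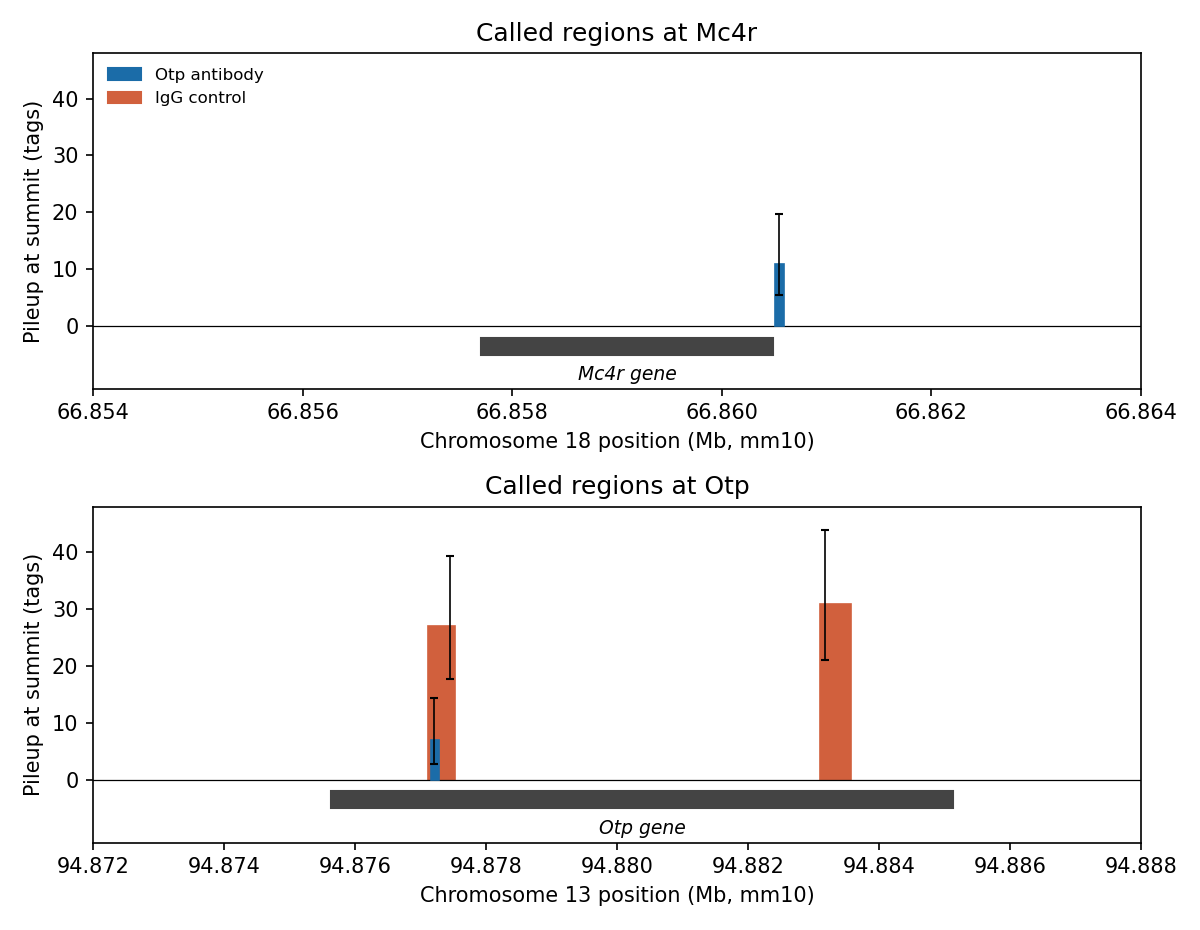
Called regions at Mc4r (top) and at the Otp gene (bottom). The horizontal axis gives the position in Mb on mm10 and the vertical axis the pileup at the summit in tags; bars span the called regions, error bars are 95% Poisson intervals and dark boxes are the genes. A region of 11 tags from the Otp library lies at the upper end of Mc4r, while both tall regions inside Otp, with 27 and 31 tags, come from the IgG control.

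To measure the background, the 2 lists were overlapped. Of the IgG regions, 280 of 291 (96.2%, 93.3 to 98.1%) overlapped an Otp region. Of the Otp regions, 280 of 11379 (2.46%, 2.18 to 2.76%) overlapped an IgG region, which left 11099 without. The regions with the highest −log10 q were shared. The 5 highest IgG regions, on chromosomes 2, 12, 14, 6 and 9, all lay at least 29496 bp from a protein-coding gene end. The region near position 103649088 of chromosome 6 had a fold enrichment of 106 in the IgG list and 113 in the Otp list, and that near position 3109873 of chromosome 12 had 96.7 and 89.0. The first 4 Mb of chromosome 9 held 38 IgG regions and 60 Otp regions. Of the 10 Otp regions with the highest −log10 q and no IgG overlap, 7 lay in this stretch, with 403 to 616 tags but a fold enrichment of 3.10 to 5.38. The other 3 lay near Sp1, 15146 bp from an end of Hdac4 (a histone deacetylase) and 62206 bp from an end of Ccnh (a cyclin). At the 226 shared regions with both pileups, the median ratio of IgG to Otp pileup was 0.305, above the 0.171 of the background values. These are regions that had also passed the threshold in the IgG library. They include mitochondrial regions, and some neighbouring IgG regions are set against the same Otp region. Of the 280 IgG regions that overlapped an Otp region, those without both pileups are left out, the 5 highest among them.

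**Figure D2:**
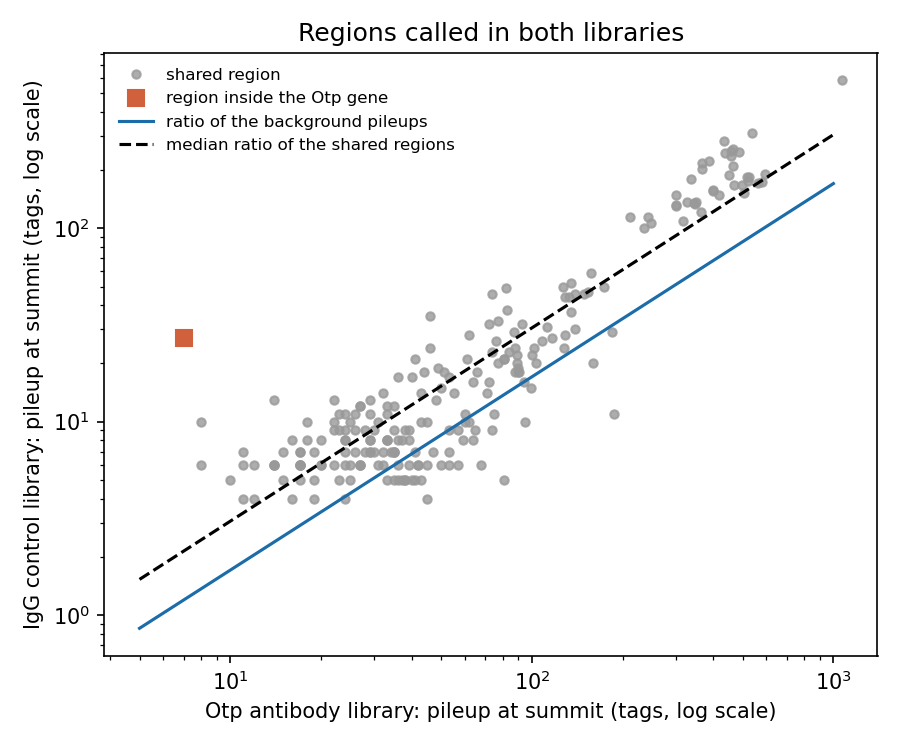
Pileup at the summit in the IgG library (vertical, tags, log scale) against the Otp library (horizontal, tags, log scale) at the 226 regions called in both with a pileup for each. The solid line is the ratio of the background values (0.171) and the dashed line the median ratio of the shared regions (0.305); the square is the shared region inside the Otp gene, at 27 IgG tags and 7 Otp tags.

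The Otp regions lay at gene ends far more often than random positions did. Of the 11354 nuclear regions, 5527 (48.7%, 47.8 to 49.6%) had their summit within 1 kb of a protein-coding gene end, against 2.98% (2.66 to 3.33%) of random positions. Within 100 bp the shares were 27.8% and 0.32%. The IgG regions gave 25.1% within 1 kb (69 of 275, 20.1 to 30.6%). A further 25.6% of Otp regions lay inside genes and 25.8% outside genes, against 38.3% and 58.7% of random positions. The share at gene ends was 33.3% for Otp regions with a −log10 q under 5 and 74.7% (72.0 to 77.2%) from 20 to 50. At 50 or more it was 29.4% (23.4 to 35.9%) of 218 nuclear regions. Of all 231 Otp regions at 50 or more, mitochondrial ones included, 62.8% overlapped an IgG region. In all, 5961 of 21887 protein-coding genes (27.2%) had an Otp region at an end, and 83 (0.379%) had an IgG region.

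The strongest Otp region at a gene end with no IgG overlap was at Sp1, a zinc finger factor that binds GC-rich promoters (chromosome 15, positions 102405618 to 102406294), with 125 tags (104 to 149) and a fold enrichment of 19.2. Next came Osbp, an oxysterol-binding protein, with 89 tags, Zbtb20, a zinc finger repressor, with 97 tags, and Evi5l with 92 tags. Pip5k1c, a lipid kinase, had 73 tags with the summit 3 bp from its lower end, and Khsrp, an RNA-binding protein, had 89 tags. Mylpf, Zfp869, Garem1, Dcaf6, Zfp317, Hip1, Agfg2, Tomm40l and Gtpbp1 completed the 15, which spanned 62 to 125 tags and fold enrichments of 15.5 to 23.5. Scaled to the IgG background, these pileups corresponded to 10.6 to 21.3 tags, above the 4 tags of the weakest IgG region with a pileup. Of the 45 gene-end regions that scaled to at least 10 tags, 6 (13.3%, 5.05 to 26.8%) overlapped an IgG region. Elsewhere 82 of 123 did (66.7%, 57.6 to 74.9%). The regions elsewhere include close neighbours, such as those at the start of chromosome 9, so their interval is too narrow.

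**Figure D3:**
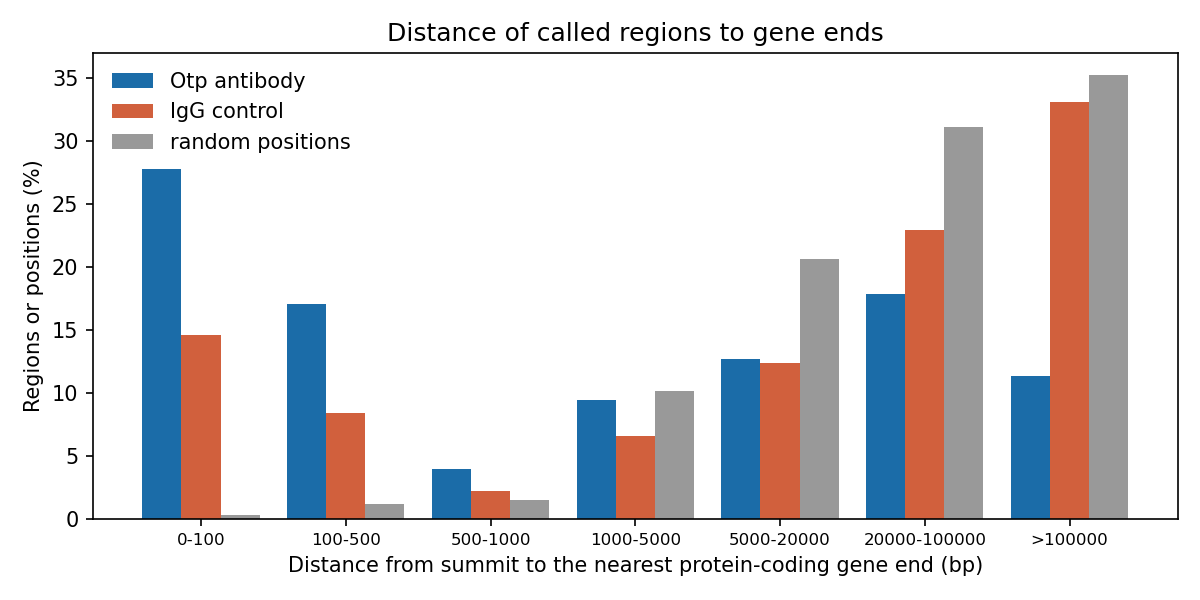
Distance from the summit to the nearest protein-coding gene end in bp (horizontal, in bins) for nuclear Otp regions, nuclear IgG regions and 10000 random positions; bars give the percentage of each set. Of Otp regions 27.8% lie within 100 bp of a gene end, against 0.32% of random positions.

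Of the 14 gene lists, housekeeping and immediate early genes had an Otp region at an end more often than length-matched genes. Glutamatergic, microglial and non-neural genes had one less often. Of the housekeeping genes, 10 of 15 had a region, against 3.99 in matched random lists (percentile 99.9). The highest were Rpl13a, a ribosomal protein, with a fold enrichment of 12.9 and 43 tags, Pgk1 of glycolysis with 9.77, the elongation factor Eef1a1 with 9.44 and Hprt of purine salvage with 9.28. Of the immediate early genes, which neuronal activity induces, 6 of 10 had a region against 2.18 (percentile 99.4). Among them were the transcription factors Jun with a fold enrichment of 10.6 and 28 tags, Egr1 with 8.06 and 25 tags and Fos with 6.90 and 14 tags, and the phosphatase Dusp1 with 6.31. None of the 15 non-neural genes had a region against 3.52 in matched lists (percentile 0.65). Nor did any of the 10 microglial genes against 2.67 (2.21) or of the 10 glutamatergic genes against 3.07 (1.28). These percentiles come from ties alone. With ties counted in full, the microglial and glutamatergic lists would lie within the range and the non-neural list still below it. At a −log10 q of at least 10, none of these 5 lists stood apart (immediate early 80.9, housekeeping 91.3, glutamatergic 10.1, microglial 11.3 and non-neural 7.67). The glutamatergic, microglial and non-neural lists still had 0 genes with a region there. No lower count was possible, so they could not have fallen below the range at that threshold. The immediate early list also left the upper range at a −log10 q of at least 5 (94.4). The glutamatergic list left the lower range within 5 kb (3.42) and when gene bodies were counted (19). The microglial list left it when gene bodies were counted (4.49). It also did within 500 bp (2.89) and at a −log10 q (3.46) or fold enrichment (2.75) of at least 5. At these last settings it still had 0 genes and could not have ranked lower. No list member had an IgG region at an end. Only 83 of all 21887 protein-coding genes (0.379%) had one, so this says little about the lists.

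Genes that define the PVN did not stand apart within 1 kb of an end. Of the 17 neuropeptide genes, 4 had an Otp region at an end, against 4.13 in matched lists (percentile 48.9). These were the thyrotropin-releasing hormone gene Trh (fold enrichment 8.01, 12 tags), the granin Scg2 (7.60, 15 tags), Nmb (5.87) and Vgf (4.90). Avp, Oxt and Crh, which encode vasopressin, oxytocin and corticotropin-releasing hormone, had none. Of the 15 transcription factors of this lineage, 4 had a region against 4.02 (percentile 51.1): the POU factors Pou3f2 (8.70, 18 tags) and Pou3f3 (7.15, 12 tags), Sim1, needed like Otp for PVN development (6.69, 12 tags), and Zfhx4 (5.92). Of the 21 energy balance genes, 4 had one against 6.28 (percentile 14.7): Mc4r, the oxytocin receptor Oxtr (6.65, 10 tags), the neurotrophin receptor Ntrk2 (6.62, 14 tags) and the prohormone convertase Pcsk1 (4.70, 7 tags). Lepr, Mc3r and Glp1r had none. At a −log10 q of at least 10, no energy balance gene had a region and the list lay below the matched range (1.82). This percentile comes from ties alone, and with ties counted in full the list would lie within the range.

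The pan-neuronal list had 6 of 15 genes with a region against 4.35 (percentile 81.4), with Syt1, a calcium sensor of synaptic vesicles, at a fold enrichment of 7.80. Of the markers of other cells and regions, 5 lists had a single gene each and lay within the matched range. These were Dlx5 of 10 GABAergic genes (percentile 9.98), Agrp of 12 genes of neighbouring hypothalamus (9.86), Aldoc of 10 astrocyte genes (8.98), Mbp of 11 oligodendrocyte genes (6.62) and Foxj1 of 9 vascular or ependymal genes (17.3). Under alternatives, 3 of these lists fell below the range. The GABAergic list did at a fold enrichment of at least 5 (2.10) and neighbouring hypothalamus within 500 bp (2.14). Both had 0 genes there, so these percentiles come from ties alone. The oligodendrocyte list did within 5 kb (2.37) and when gene bodies were counted (1.29). Of the 39 list genes with a region, 4 had one that lay nearer to an end of another gene: Agrp (98 bp from Atp6v0d1), Aldoc (66 bp from Pigs), Nmb (2 bp from Wdr73) and Sdha (1 bp from Ccdc127).

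**Figure D4:**
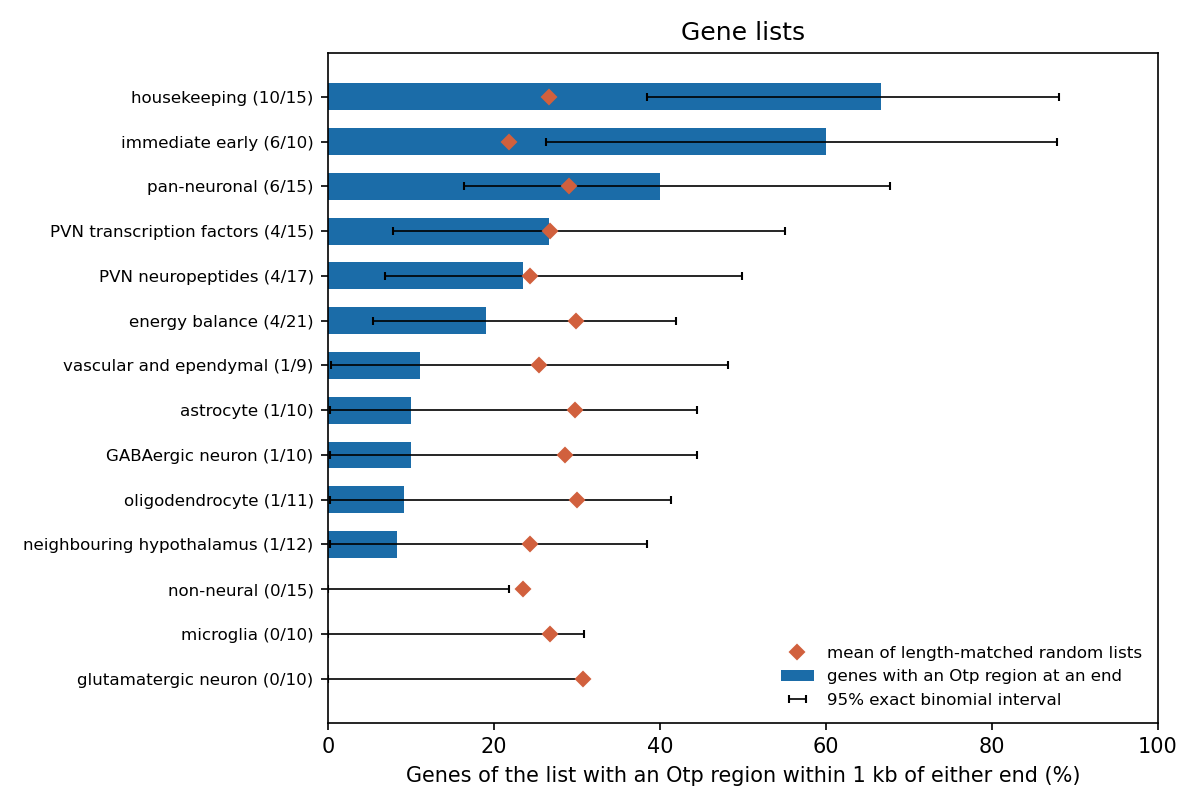
Percentage of genes in each list with an Otp region within 1 kb of either end (horizontal axis), with the counts beside each name. Bars are the observed shares, error bars 95% exact binomial intervals, and diamonds the mean of 10000 random lists matched on gene length; housekeeping genes reach 66.7% against 26.6%, while PVN neuropeptides (23.5% against 24.3%) sit near their matched mean.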

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

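A −log10 q of at least 10 left 3932 Otp and 174 IgG regions, removed the region at Mc4r (0 left), and put 0 gene lists above and 1 below the matched range. The 1 below was the energy balance list (percentile 1.82), which lay within the range at first. It had 0 genes there, so its percentile comes from ties alone. With ties counted in full it would lie within the range. None of the 5 lists that had stood apart still did. The glutamatergic, microglial and non-neural lists also had 0 genes there and could not have ranked lower. With a −log10 q of at least 5, 1 list lay above it. The region at Mc4r was kept with windows of 500 bp and 5 kb, at a −log10 q of at least 5 and at a fold enrichment of at least 5. The share of Otp regions overlapping an IgG region was 1.56% with a reciprocal overlap of 50%, 4.32% at a −log10 q of at least 10, and 56.0% among regions whose pileup scaled to at least 10 IgG tags, a setting chosen after seeing the data. The share of Otp regions at gene ends was 44.8% within 500 bp, 58.1% within 5 kb, 54.0% at the ends of all annotated genes, 53.7% and 64.7% at a −log10 q of at least 5 and 10, 49.7% at a fold enrichment of at least 5 and 26.8% among regions that scaled to at least 10 tags. Random positions gave 1.51% within 500 bp, 13.1% within 5 kb and 6.21% at all annotated genes. Of 112 list percentiles under alternatives, 95 stayed on the same side of the bounds, 12 moved inside and 5 moved outside. Total depth is unknown, and the low IgG background limits any comparison at regions of few tags. The motif search and the matching on CpG density were not run. No paired analysis was possible because each group has 1 library, and no library could be left out.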

Other observations

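The tests below were chosen after the results were seen, except the percentiles of the PVN lists, which were planned. Families of genes grouped by symbol extended the pattern of the housekeeping list. Cytosolic ribosomal proteins had an Otp region at an end in 52 of 84 genes (61.9%, 95% interval 50.7 to 72.3%), against 19.1% in length-matched genes. Mitochondrial ribosomal proteins had one in 39 of 75 genes (52.0% against 25.1%), led by Mrps9 with 21.3 and 44 tags. Complex I of the respiratory chain had one in 25 of 49 genes (51.0% against 25.7%) and the proteasome in 20 of 39 (51.3% against 28.8%). Zinc finger genes named Zfp had one in 167 of 397 (42.1% against 31.0%).

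Other families had fewer regions than matched genes. None of the 1106 olfactory receptor genes had an Otp region at an end, against 11.6% in matched genes. Of the 39 Hox genes, Hoxb8 alone had one (2.56% against 23.4%). Potassium channel genes, many of which neurons express, had one in 14 of 94 (14.9% against 29.7%), among them Kcnn3 with a fold enrichment of 11.9.

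Most Otp regions at gene ends overlapped no IgG region, and the IgG background was 5.86 times lower. For the strongest regions, depth alone is argued against. Of the 45 gene-end regions that scaled to at least 10 IgG tags, 13.3% overlapped an IgG region, with an upper bound of 26.8%. Elsewhere 66.7% of such regions did, but these are not matched on pileup. They include chromosome 9 regions of 403 to 616 tags, whereas the 15 regions named at gene ends had 62 to 125. Scaling by the ratio of 0.305 at shared regions gave 29 of 490 (5.92%) at gene ends and 119 of 273 (43.6%, 37.6 to 49.7%) elsewhere. From 4 to 10 tags by background, 41 of 1151 gene-end regions (3.56%, 2.57 to 4.80%) overlapped an IgG region, against 52 of 346 (15.03%, 11.4 to 19.2%) elsewhere and 16 of 188 (8.51%, 4.94 to 13.5%) of those inside genes. By the ratio at shared regions, the shares from 4 to 10 tags were 1.07% (0.73 to 1.52%) at gene ends, 2.17% (1.49 to 3.05%) elsewhere and 2.11% (1.25 to 3.31%) of those inside genes, with intervals that meet. Depth therefore stays open from 4 to 10 tags, since the result rests on the scaling. For 4281 of the 5477 gene-end regions with a pileup, or 2099 by the ratio at shared regions, Mc4r among both, the scaled value lay below the 4 tags of the weakest IgG region with a pileup. Of the 4281, 0.42% overlapped an IgG region, against 0.403% of such regions elsewhere. Below 4 scaled tags, Otp signal and cutting that IgG would also show cannot be told apart, because too few regions reach the IgG list.

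The 2 IgG regions inside the Otp gene are the pattern that most needs a second look, because the control has no target there. Background shared by both libraries would have given about 158 tags in the Otp library at the first region (88.4 by the ratio at shared regions), and 7 were seen with an upper bound of 14.4. Counting noise was compared as well: 7 tags scale to 1.19 in the IgG library (2.14 by the ratio at shared regions). There 27 were seen with a lower bound of 17.8. The region was listed because it stood above its background, so this outcome was largely fixed in advance and decides nothing. The bound also takes tags as independent, which reads amplified by PCR are not. The excess of 22.6 over the scaled Otp pileup was the highest of the 226 shared regions, and the next was 7.33. Whether the IgG library holds DNA carrying Otp sequence from outside the nuclei, and whether the regions match exons, was not tested here.

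Housekeeping genes had an Otp region at an end more often than matched genes, while the PVN lists did not. Among the mitochondrial ribosomal proteins, none of which is in the housekeeping list, the share was 52.0% (40.2 to 63.7%). Cutting at promoters that are open in most cells would give such an excess. Otp signal at the same promoters would give it too, so this share cannot tell them apart. Otp binding directed to PVN genes stays open: the higher percentile of the neuropeptide and transcription factor lists was 51.1. With windows of 5 kb the transcription factor list reached 93.6 and the neuropeptide list 43.0. Within 500 bp these lists, in that order, lay at 59.4 and 15.8. At a −log10 q of at least 10 they lay at 26.6 and 6.09, the latter with 0 genes. Without a motif search or a map of open chromatin, these explanations cannot be separated for the region at Mc4r.

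Of the 11 IgG regions that overlapped no Otp region, 1 lay in Otp and 1 on the mitochondrial genome. The other 9 had at most 8 tags. The mitochondrial genome held 25 Otp and 16 IgG regions.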
